A study of Rattus norvegicus with 72 samples.

How the data were processed

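The series holds 72 libraries from female rat pups taken on postnatal day 2 (P2) or 9 (P9), per the labels. Pups carried a UBE3A deletion derived from the mother or from the father, or were litter-matched wild-type (WT) controls. Of these libraries, 48 are RNA libraries (24 from hypothalamus and 24 from cortex, in 16 groups of 3) and 24 are whole-genome bisulfite DNA libraries from hypothalamus. The DNA groups labelled maternal hold 3 WT and 3 deletion libraries at P2 and 2 and 2 at P9, and those labelled paternal hold 4 and 4 at P2 and 3 and 3 at P9. Groups were taken from the labels for parent of origin, age, genotype and tissue, and a library is called "labelled maternal" or "labelled paternal" after its parent-of-origin label, WT littermates included. Replicates are treated as separate samples because the labels list them so. No label ties a library to a litter, a batch or another library, so p-values measure the spread between these samples. Replicate numbers were assigned here, in the order of the sample records within a group. They only name a library and pair nothing. Library names fall into series by their leading digit, and these were used as the only hint of a batch. Hypothalamus RNA libraries are of a single series (JL2). In cortex all RNA libraries labelled maternal are of the series JL6 and all labelled paternal of the series JL7, so parental label and name series cannot be told apart there.

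RNA libraries were made with rRNA depletion and a directional kit, and DNA libraries with a TruSeq DNA methylation kit, per the labels' protocols. STAR and the genome builds rn6 and Rnor_6.0 are named per the submitters' processing notes. The read counter, its annotation, the strand setting, the aligner of the bisulfite reads and the region caller are not given in the sources used here. The deposited RNA tables hold raw whole-number counts per RefSeq accession, 184444 per tissue, of which 168377 start with NM_ (mRNA) and 16067 with NR_ (noncoding RNA). The deposited methylation tables hold 1 smoothed methylation level per region and library as a fraction from 0 to 1, per the file headers, with no read coverage. They also hold, per the file headers, the authors' region coefficient and its statistic (a score), the authors' p-value and q-value, and the number of CpG sites in the region. There are 3 such tables, here called the control, maternal and paternal tables, with 12 libraries each. No per-sample column was left unmapped (0 columns).

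The accessions were looked up in a RefSeq table of rat genes (assembly GRCr8, 114702 distinct accessions), and 0 of the 184444 matched. The files do not pair accessions with gene names, so accessions are given as deposited, at most a pair in each direction per comparison. The rat Ube3a accessions of that table were also not among the accessions of the files (0 matches). Only rat accessions were looked up, so whether any counted accession, NM_173010 included, stands for the deleted gene is open, and the genotype and parental labels were taken as given without a check by that gene. Of 665 gene symbols in 29 gene lists, 652 had a rat accession and 0 of these were counted, so no list was tested and the planned set tests gave no value. Several accessions can belong to the same gene. Counts whose summed difference from another tested accession's over all libraries was under 10% of the larger total were found for 377 accessions in hypothalamus (6.46%) and 1611 in cortex (19.2%), so counts of accessions are not counts of genes.

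RNA totals per library ran from 218288 to 1165651 counts in hypothalamus (median 565565) and from 735159 to 2498255 in cortex (median 1385697). In R 4.3.3, each tissue's 24 libraries were fitted together in edgeR 4.0.16, with TMM scaling, the filterByExpr filter on low counts, 1 mean per group and robust quasi-likelihood dispersion. The filter kept 5840 accessions in hypothalamus and 8380 in cortex. They held 95.1% to 97.4% and 97.2% to 98.9% of each library's counts. The common biological coefficient of variation was 22.3% in hypothalamus and 13.3% in cortex, with 16 residual degrees of freedom. Contrasts were tested with the quasi-likelihood F-test, two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes come with standard errors and 95% intervals from the same fit. Levels are given as CPM, the count scaled to TMM-adjusted library size. None of the 48 pairs of replicates held identical counts, and the lowest chi-square per degree of freedom between replicates was 1.56, so no library was counted as a repeat of another.

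Smoothed levels were tested per region with limma 3.58.1 (eBayes with a variance trend), with age or kind of litter as a covariate and Benjamini-Hochberg adjustment. Regions tested numbered 16243 in the control table, 18335 in the maternal table and 13874 in the paternal table. A single region of the control table and a single region of the paternal table had no levels. Regions had a median of 6 CpGs. Because the depth behind a level is unknown and levels are smoothed over neighbouring CpGs, no counting interval is given, and because each table lists candidate regions chosen for its own comparison, p-values can be too small. Library means over all regions were compared by exact permutation of labels within strata, two-sided. Coordinates are as deposited, on the build named per the submitters' processing notes (rn6), and no annotation of that build was used here.

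The tables and the labels do not match in full. The maternal table holds 8 libraries labelled maternal and 4 labelled paternal, and the paternal table has 10 labelled paternal and 2 labelled maternal. Those 4 are all labelled P2 and stand, in column order, among the libraries labelled P9. Those 2 are all labelled P9 and stand among the libraries labelled P2. Their age labels may thus be in doubt as well. Some of them are WT libraries of the control table, so the doubt reaches the litter and age tests there. Deletion was tested in the 8 and the 10, with litters by label, in place of the 10 and 14 libraries planned. The control table holds 5 WT libraries labelled maternal and 7 labelled paternal. Across regions, the library difference by genotype label had a Pearson r of 0.654 with the authors' coefficient in the authors' deposited table for both deletion comparisons when all 12 libraries were used. In the control table, whose direction the headers do not give, the difference by parental label had an r of -0.365 with the coefficient of the authors' deposited table, and the difference by table membership (libraries also in the maternal table against those also in the paternal table) an r of -0.653. The deposited comparison of WT litters thus followed the tables more closely than the labels used here. Regions are not independent replicates.

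Tests, samples, covariates, the rule for naming accessions and most alternatives were chosen before the data were examined. That rule took accessions past the threshold with at least 1 CPM in a group and, for deletion, with all libraries of a group on the same side of the other group's. It was then narrowed to the largest rises and falls, at most 2 each, because the accessions carry no names, and the 3 accessions of lowest p in comparisons with few calls are not listed for the same reason. For methylation it took called regions, or the 3 of lowest p as values. The tests within each kind of litter, of deletion pups by age and litter, the age score, the shares of NR_ accessions and the values of NM_172412, and of NM_173010 and NM_027915 outside the comparisons that named them, were chosen after the data were seen.

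The alternatives were size factors of the DESeq2 type in place of TMM, the Wald test of DESeq2 1.42.0, no filter on low counts, only the libraries of the contrast, and each library left out in turn. Added after seeing the data were removal of the most abundant hypothalamic accession before scaling, and thinning of all libraries of a tissue to the lowest total. For methylation they were the logit scale, no variance trend, no covariate, only regions with mean levels from 0.1 to 0.9, library name series as a covariate and, added later, other choices of libraries and groupings.

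Each pipeline was tested on simulated data drawn from the real means, with 200 changed accessions or regions. For the maternal P9 deletion contrast in hypothalamus (5617 accessions), 10 of 66 accessions changed 2-fold (15.2%) and 46 of 65 changed 4-fold (70.8%) were called, with 1 false call. The matching figures in cortex (7833 accessions) were 30 of 65 (46.2%) and 57 of 64 (89.1%), with 11 false calls. A shift of 0.2 in the methylation level was called in 36% of changed regions in the maternal table and 61.5% in the paternal table for deletion, and in 70% for litters and 72% for age in the control table.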

Results

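Hypothalamus and cortex of female rat pups were profiled to compare the loss of Ube3a inherited from the mother with the loss inherited from the father. Ube3a encodes an E3 ubiquitin ligase that in neurons is expressed mainly from the maternal allele. RNA was sequenced in 48 libraries, 3 for each combination of tissue, parental label, age (P2 or P9) and genotype. Bisulfite sequencing covered 24 hypothalamus DNA libraries. The series description gives RNA and DNA of hypothalamus a shared sample of origin, but no label says which libraries match, and groups labelled paternal at P2 hold 4 DNA and 3 RNA libraries. Depth differed between the kinds of litter. In hypothalamus, totals ran from 218288 to 599865 counts in libraries labelled maternal and from 437650 to 1165651 in those labelled paternal. In cortex they ran from 1669200 to 2498255 in libraries labelled maternal and from 735159 to 1102194 in those labelled paternal. The most abundant hypothalamic accession, NR_137294, took a mean of 14.7% of counts at P2 and 18.4% at P9 in libraries labelled maternal, and 6.20% and 7.53% in those labelled paternal (n = 6 each). Because no accession matched a rat gene in the table used, accessions stand without names. Whether any of them is the deleted gene is not settled by the files, so parental and genotype labels were used as given, without a check by that gene.

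In hypothalamus of pups labelled paternal, a single accession, NM_173010, was lower with the deletion, and it was lower at both ages. At P2 its level was 51.4 ± 6.11 CPM in WT and 7.89 ± 1.41 CPM in deletion libraries (SD, n = 3 each). At P9 the levels were 46.2 ± 8.22 and 5.49 ± 2.50 CPM (SD, n = 3 each). Every deletion library lay below every WT library at both ages. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change of NM_173010 was -2.66 (SE 0.359, adjusted p = 0.000261) at P2 and -2.89 (SE 0.399, adjusted p = 0.000394) at P9. Over both ages NM_173010 fell by 2.77 on the log2 scale (SE 0.268, 95% interval -3.32 to -2.23), a 6.84-fold difference, with an edgeR quasi-likelihood adjusted p of 2.52e-07 after Benjamini-Hochberg adjustment. Its deletion effect at P9 minus that at P2 was -0.23 (95% interval -1.36 to 0.91), so the ages were not told apart for NM_173010. The files do not say whether NM_173010 belongs to the deleted gene. With only the libraries of the contrast, the log2 fold change of NM_173010 at P9 was -2.90 and its adjusted p 0.147 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With all libraries thinned to the lowest total, chosen after seeing the data, its log2 fold change was -1.38 at P2, -2.50 at P9 and -1.94 over both ages, with adjusted p of 0.949, 0.407 and 0.198 by the same edgeR quasi-likelihood test and Benjamini-Hochberg adjustment.

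Other accessions of the hypothalamus labelled paternal did not pass the threshold. At unadjusted p under 0.05 there were 123 of 5840 at P2 and 50 at P9, where evenly spread p-values give 292. Without WT replicate 1 at P9 the count at P9 was 288, about as many as evenly spread p-values give. The low count at P9 thus depended on that library, and these counts show neither an effect nor a lack of effect. DESeq2's Wald test called 1 accession at each age and 2 over both ages. The age dependence of the deletion effect gave 0 calls in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and 0 in DESeq2, with 90 at unadjusted p under 0.05.

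In hypothalamus of pups labelled maternal, NM_173010 did not differ beyond the spread between libraries. It stood at 56.9 ± 26.2 CPM in WT and 53.0 ± 19.4 CPM in deletion libraries at P2, and at 41.7 ± 10.95 and 38.5 ± 14.2 CPM at P9 (SD, n = 3 each). The log2 fold change of NM_173010 over both ages was -0.13 (SE 0.26, 95% interval -0.66 to 0.40). The test of the difference itself, the deletion effect labelled maternal minus that labelled paternal, gave 2.64 on the log2 scale for NM_173010 (SE 0.378, adjusted p = 0.000775 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It was the only accession past the threshold for that difference in edgeR, with 78 at unadjusted p under 0.05, and DESeq2 also called 1. Thinned to the lowest total, the difference for NM_173010 was 1.67 and its adjusted p 1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

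**Figure D1:**
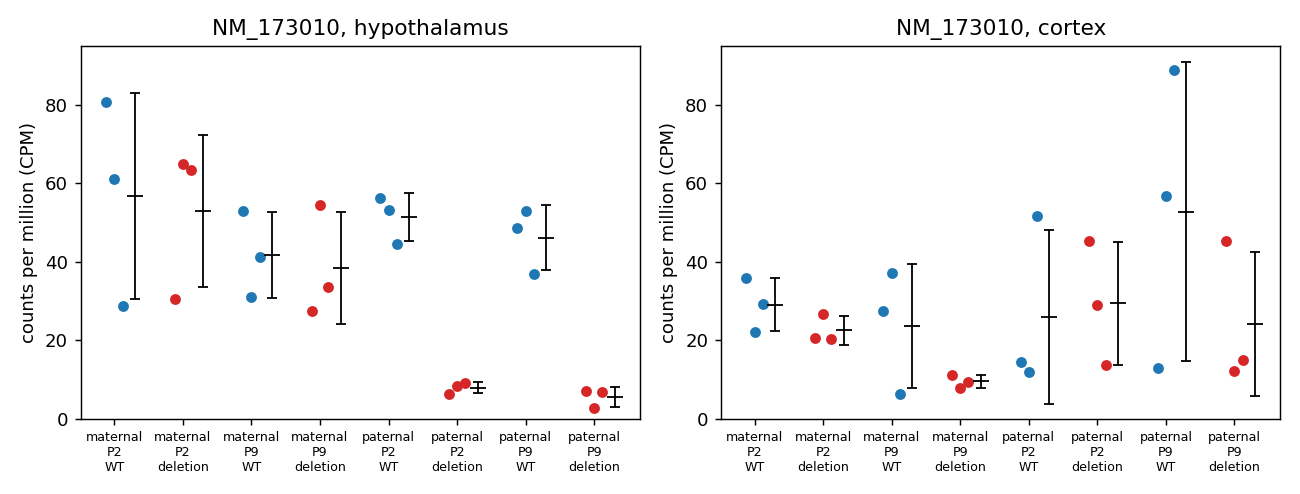
Level of accession NM_173010 in CPM (vertical axis) in each RNA library of hypothalamus (left) and cortex (right), by parental label, age and genotype (horizontal axis; blue WT, red deletion). Points are libraries and bars are mean and SD (n = 3); in hypothalamus labelled paternal the deletion libraries lie between 2.61 and 9.07 CPM and the WT libraries between 37.0 and 56.3 CPM. In every other pair of groups the ranges of WT and deletion libraries overlap.

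No accession passed the threshold for the deletion labelled maternal in hypothalamus. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 at P2, with 97 of 5840 at unadjusted p under 0.05 and 0 by DESeq2. At P9 it called 0, with 172 at unadjusted p under 0.05, a lowest adjusted p of 0.142 and 1 call by DESeq2. Over both ages it called 0, with 145 at unadjusted p under 0.05 and 0 by DESeq2, and the age dependence gave 0, with 146 at unadjusted p under 0.05 and 0 by DESeq2. All these counts lie below the 292 that evenly spread p-values give. The p-values here thus ran large, and the low counts are no sign that the deletion had no effect. In data simulated for the P9 contrast, 15.2% of 2-fold changes and 70.8% of 4-fold changes were called, so most 2-fold changes would be missed in this design.

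In cortex, NM_173010 varied between libraries of the same group and was not called. Among libraries labelled paternal at P9, WT stood at 52.8 ± 38.1 CPM and deletion at 24.2 ± 18.4 CPM, and among those labelled maternal at P9, WT stood at 23.7 ± 15.8 and deletion at 9.51 ± 1.67 CPM (SD, n = 3 each). The log2 fold changes of NM_173010 were -0.36 and -1.29 at P2 and P9 with the label maternal, and 0.23 and -1.06 with the label paternal. WT replicate 3 labelled maternal at P9 had 6.29 CPM of NM_173010, below the 3 deletion libraries (7.87 to 11.2 CPM), and the other WT libraries of that group had 27.5 and 37.2 CPM. With the label paternal, high and low levels of NM_173010 occurred in both genotypes: at P2 WT libraries had 14.5, 11.95 and 51.6 CPM and deletion libraries 45.3, 29.0 and 13.8 CPM, and at P9 WT libraries had 12.96, 56.7 and 88.8 CPM and deletion libraries 45.3, 12.2 and 15.1 CPM. NM_173010 thus did not separate the labelled genotypes in cortex as it did in hypothalamus labelled paternal. The genotype labels of cortex were not checked by any other means, and deletion folds and counts in cortex, zeros included, hold only as far as these labels do.

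No accession of the cortex passed the threshold for deletion in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For the label maternal there were 0 calls at P2 (270 of 8380 at unadjusted p under 0.05, 1 by DESeq2), 0 at P9 (784 at unadjusted p under 0.05, 9 by DESeq2) and 0 over both ages (758 at unadjusted p under 0.05, 9 by DESeq2). The lowest adjusted p of edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment was 0.0593 at P9. For the label paternal there were 0 calls at P2 (275 at unadjusted p under 0.05, 0 by DESeq2), 0 at P9 (495 at unadjusted p under 0.05, 1 by DESeq2) and 0 over both ages (448 at unadjusted p under 0.05, 0 by DESeq2). Chance alone gives 419 at unadjusted p under 0.05. The maternal minus paternal difference had 0 calls in edgeR, 681 at unadjusted p under 0.05 and 3 calls by DESeq2, and the age dependence had 0 with each label, with 350 (maternal) and 357 (paternal) at unadjusted p under 0.05 and 0 by DESeq2. Without WT replicate 3 labelled maternal at P9, edgeR called 321 accessions at P9 (12 rose and 309 fell), 220 over both ages and 52 for the parental difference, and without WT replicate 2 labelled paternal at P9 it called 13 for the label paternal at P9. Without filtering low counts, 56 were called at P9 with the label maternal and 15 with the label paternal.

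WT libraries with different parental labels also differed, which is the background for any comparison of these labels. In hypothalamus, 47 accessions were higher and 26 lower in WT libraries labelled maternal than in those labelled paternal, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Totals of these WT libraries did not overlap, at 265462 to 599865 counts with the label maternal and 685454 to 1165651 with the label paternal. Kind of litter thus goes together with depth here, and the main fit cannot tell them apart. NM_029872 was higher at 127 ± 51.5 CPM against 16.8 ± 11.2 at P2 and 74.0 ± 28.8 against 14.2 ± 3.51 at P9 (SD, n = 3 each), a log2 difference of 2.60 (SE 0.278, edgeR quasi-likelihood adjusted p = 2.43e-06 after Benjamini-Hochberg adjustment). NM_008427 was higher by 2.98 (SE 0.579), and NM_001132452 (-2.55, SE 0.589) and NM_025769 (-1.77, SE 0.422) were lower. Calls depended on the filter, the method, depth and single libraries. With no filter on low counts 49 were higher and 295 lower, which turns the balance of directions, DESeq2's Wald test called 178, and 18 were called with all libraries thinned to the lowest total. With a library left out the count ran from 9 without WT replicate 2 labelled paternal at P2 to 344 without WT replicate 1 labelled paternal at P9, NM_008427 lost its call in 3 of 12 such fits (log2 difference 1.91 without WT replicate 1 labelled maternal at P2), and NM_001132452 and NM_025769 lost theirs in 10 and 8 of 12 such fits. The same comparison in deletion pups, chosen after seeing the data, gave 133 higher and 101 lower accessions, and 43 accessions were called in both, all in the same direction.

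In cortex the same WT comparison called 541 accessions higher and 862 lower in libraries labelled maternal, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Parental label and library name series (JL6 maternal, JL7 paternal) coincide in cortex RNA, so this difference, and any other between parental labels in cortex, cannot be told apart from one between the series. NR_015466 was higher by 2.08 (SE 0.476) and NM_028748 by 1.83 (SE 0.503). NR_074088 was lower (-2.92, SE 0.586), at 0.163 ± 0.282 CPM against 5.14 ± 0.739 with the label paternal at P2 and 2.37 ± 0.921 against 6.97 ± 1.26 CPM at P9 (SD, n = 3 each). NM_001316345 was also lower (-2.62, SE 0.455). The filter kept NR_074088 and NM_001316345 in only 6 of 12 fits with a library left out. The balance of directions depended on the libraries and the filter: without WT replicate 1 labelled paternal at P2 there were 660 higher and 455 lower, and with no filter on low counts 1852 higher and 477 lower. With all libraries thinned to the lowest total, 547 accessions were called. In deletion pups, 1263 were higher and 1846 lower, and 1216 accessions were called in both genotypes, all in the same direction. Between tissues, 15 accessions were called in both, 13 of them in the same direction, where independent lists give 6.77 in the same and 7.22 in opposite directions.

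Noncoding accessions were unevenly spread over these calls. Among the 862 accessions lower in cortex labelled maternal, 264 (30.6%) were NR_ accessions, against 7.89% of all others tested (odds ratio 5.15, 95% interval 4.34 to 6.11, Fisher's exact test, adjusted p = 3.15e-70). Among the 541 that were higher, 1.29% were NR_ accessions, against 10.8% of the others. In the libraries themselves, NR_ accessions other than NR_137294 took 9.52% ± 0.765 of counts in cortex labelled paternal at P9, 6.51% ± 0.351 at P2, and 6.53% ± 0.261 (P2) and 4.95% ± 0.514 (P9) in cortex labelled maternal (SD, n = 6 each, both genotypes). In hypothalamus the share was 6.83% at P2 and 5.11% at P9 with the label maternal, and 7.23% and 6.32% with the label paternal. Only cortex labelled paternal thus had the higher share at P9, and its age labels may be exchanged, as weighed below. An exchange would make its shares 9.52% at P2 and 6.51% at P9. Accessions of the same gene are not independent, so the p-values of Fisher's test are too small.

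Age changed many accessions in hypothalamus. Between P2 and P9, 435 rose and 328 fell in WT libraries averaged over the kinds of litter (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Without WT replicate 1 labelled maternal at P2 the count was 465 in place of 763, and with all libraries thinned to the lowest total it was 228 (136 rose and 92 fell). NM_008614 had 0 to 4 counts in the 6 WT libraries at P2 and 8 to 434 at P9, with levels of 370 ± 427 CPM (labelled maternal) and 144 ± 202 CPM (labelled paternal) at P9 (SD, n = 3 each). NM_080451 rose (adjusted p = 0.00311) and NM_001040689 fell (adjusted p = 0.0144) in the averaged comparison by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the label maternal, NM_080451 had no counts at P2 and 15.8 ± 13.2 CPM at P9, and NM_001040689 had 8.61 ± 4.35 CPM at P2 and no counts at P9, so no fold is given for either (SD, n = 3 each). With the label paternal, NM_080451 had 5.68 ± 2.81 and 17.4 ± 5.51 CPM and NM_001040689 16.3 ± 5.18 and 6.94 ± 3.52 CPM (SD, n = 3 each). NM_027915 was at 88.0 ± 45.5 CPM at P2 and 2.16 ± 2.22 at P9 with the label maternal and at 28.2 ± 47.6 and 1.61 ± 2.08 CPM with the label paternal (SD, n = 3 each). Averaged over the kinds of litter it fell by 4.73 on the log2 scale (SE 1.42, adjusted p = 0.0368 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). That averaged call was lost in 10 of 12 fits with a library left out, with adjusted p up to 0.698 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and the log2 change was -2.19 without WT replicate 2 labelled paternal at P2. Within a kind of litter, NM_080451 passed the threshold with the label maternal (adjusted p = 0.0333) and not with the label paternal (0.132), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. NM_008614 (adjusted p = 0.0807 maternal and 0.0545 paternal), NM_027915 (0.217 and 0.198) and NM_001040689 (0.0909 and 0.206) passed it in neither by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Tested within each kind of litter, 139 accessions rose and 75 fell with the label maternal, and 220 rose and 127 fell with the label paternal. Of these, 111 were called in both and all 111 moved in the same direction. The difference in age effect between the kinds of litter gave 0 calls in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 285 at unadjusted p under 0.05; DESeq2 was not run on it.

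In cortex the averaged age comparison called 0 accessions in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 669 at unadjusted p under 0.05 and 1 call by DESeq2. Within each kind of litter, however, changes were many and opposite. With the label maternal 1425 accessions rose and 1142 fell from P2 to P9, and with the label paternal 1145 rose and 1312 fell. The litters shared 1580 called accessions, of which 0 moved in the same direction and 1580 in opposite directions, where independent lists give 374 and 379. A test of the difference in age effect between the litters called 3876 of 8380 accessions (1918 higher and 1958 lower). Across accessions, the log2 age effects of the litters had a Pearson r of -0.730. In deletion pups the pattern was the same, with 1646 shared calls, all in opposite directions.

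NM_172412 shows the opposition. In WT cortex labelled maternal it went from 99.6 ± 20.0 CPM at P2 to 5.38 ± 3.39 CPM at P9, and in WT cortex labelled paternal from 6.67 ± 3.95 to 93.0 ± 10.8 CPM (SD, n = 3 each). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 changes of NM_172412 were -4.18 (SE 0.31, adjusted p = 4.91e-11) and 3.74 (SE 0.357, adjusted p = 7.86e-09). In hypothalamus NM_172412 fell by 3.19 with the label maternal and fell by 2.88 with the label paternal, from 20.6 ± 7.44 to 2.74 ± 4.75 CPM and from 36.9 ± 7.40 to 5.11 ± 2.67 CPM (SD, n = 3 each). NM_008614 likewise stood at 0.651 ± 1.13 CPM (P2) and 163 ± 72.1 CPM (P9) in WT cortex labelled maternal, and at 101 ± 59.7 CPM (P2) and 0.309 ± 0.535 CPM (P9) in that labelled paternal (SD, n = 3 each).

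Set against the hypothalamus, the age effect of cortex labelled maternal ran in the same direction and that of cortex labelled paternal ran in reverse. Of accessions called for age in hypothalamus and in cortex labelled maternal, 538 moved in the same direction and 6 in the opposite one. For cortex labelled paternal, 3 moved in the same direction and 554 in the opposite one. An age score, the mean signed deviation in log2 CPM over accessions called for age in hypothalamus, was 0.53 ± 0.04 at P9 and -0.33 ± 0.06 at P2 in cortex labelled maternal, a difference of 0.86 (SD, n = 6 each, both genotypes). In cortex labelled paternal it was -0.59 ± 0.09 at P9 and 0.38 ± 0.05 at P2, a difference of -0.97 (SD, n = 6 each). Each difference had an exact two-sided permutation p of 0.00216, the smallest that 924 arrangements can give (0.00216 after Benjamini-Hochberg adjustment over the 4 scores computed). All 6 libraries of an age lay on the same side of the 6 of the other age in both. In hypothalamus, where the accessions were chosen, the differences were 0.84 and 0.82 with the labels maternal and paternal and are no independent test.

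**Figure D2:**
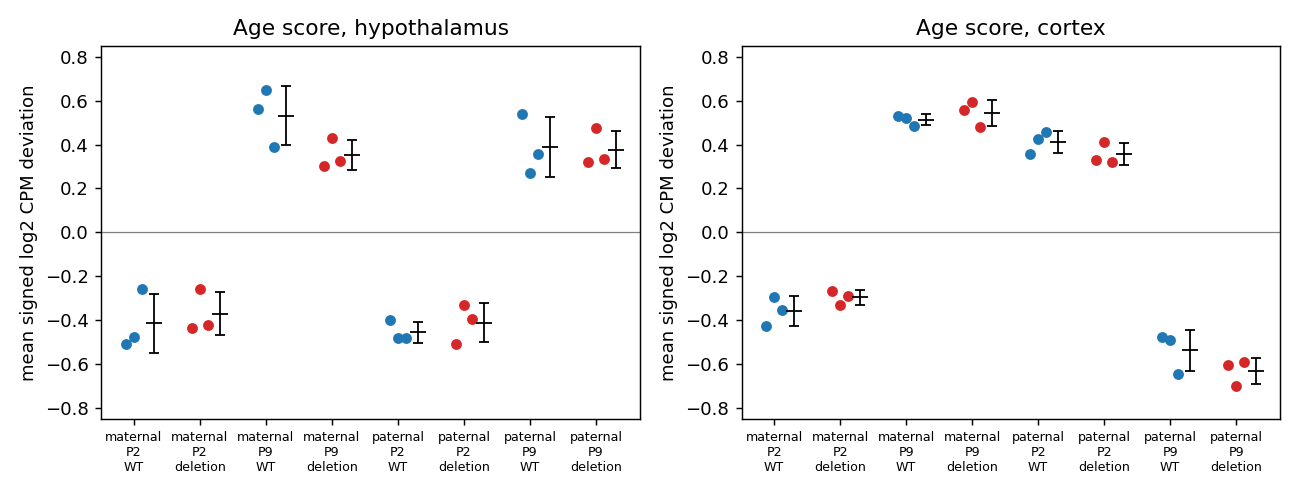
Age score (vertical axis, mean signed log2 CPM deviation over accessions called for age in hypothalamus) of each RNA library in hypothalamus (left) and cortex (right), by parental label, age and genotype (horizontal axis; blue WT, red deletion). Points are libraries and bars are mean and SD (n = 3); P9 libraries lie above P2 libraries everywhere except in cortex labelled paternal, where P2 libraries lie between 0.32 and 0.46 and P9 libraries between -0.70 and -0.48.

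Methylation was compared in hypothalamus over candidate regions with a median of 6 CpGs. For the deletion labelled maternal (4 against 4 libraries), the lowest p values belonged to regions on chromosomes 4, 14 and 10. Each group of 4 held a single library labelled P9, and the rest were labelled P2, so P9 has no replicates here. The region on chromosome 14 from 42217787 to 42218214 (6 CpGs) had a level of 0.370 ± 0.169 in deletion and 0.780 ± 0.0970 in WT libraries (SD, n = 4 each). The region on chromosome 4 from 146367230 to 146367607 (5 CpGs) had 0.801 ± 0.0277 and 0.939 ± 0.0378, and that on chromosome 10 from 106298383 to 106299687 (9 CpGs) had 0.596 ± 0.113 and 0.831 ± 0.0220 (SD, n = 4 each). None passed the threshold: limma with Benjamini-Hochberg adjustment called 0 of 18335 regions, with 1393 at unadjusted p under 0.05 and a lowest adjusted p of 0.610. The authors' deposited maternal table holds 12 libraries, 6 deletion and 6 WT, of which 4 are labelled paternal, so its values are not of the same groups. In that authors' deposited table no region (0) had a q under 0.05, the lowest q was 0.196 and 876 regions had a p under 0.05.

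For the deletion labelled paternal (5 against 5 libraries), the region on chromosome 1 from 36750550 to 36750750 (29 CpGs) had a level of 0.425 ± 0.207 in deletion and 0.773 ± 0.133 in WT libraries (SD, n = 5 each). On chromosome 9, the region from 114732649 to 114733299 (6 CpGs) had 0.818 ± 0.0241 and 0.946 ± 0.0299, and the region from 10949456 to 10950402 (16 CpGs) had 0.252 ± 0.0715 and 0.501 ± 0.0415 (SD, n = 5 each). These 3 had the lowest p, and none passed the threshold: limma with Benjamini-Hochberg adjustment called 0 of 13874 regions, with 1056 at unadjusted p under 0.05 and a lowest adjusted p of 0.149. In the authors' deposited table, which holds 6 deletion and 6 WT libraries with 2 labelled maternal among them, no region (0) had a q under 0.05, the lowest q was 0.956 and 617 regions had a p under 0.05. With all 12 libraries of the table, chosen after seeing the data, 1 region was called, that from 114732649 on chromosome 9.

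Between WT litters, a single region was called. It lay on chromosome 11 from 34351283 to 34351588 (9 CpGs), with a level of 0.756 ± 0.110 in libraries labelled maternal (SD, n = 5) and 0.370 ± 0.0572 in those labelled paternal (SD, n = 7). The age-adjusted difference was 0.385 (SE 0.0525, limma adjusted p = 0.00702 after Benjamini-Hochberg adjustment), and 1091 of 16243 regions had an unadjusted p under 0.05. Tables and parental labels differ for some of these libraries. In the authors' deposited table that region had a p of 0.153 and a q of 0.967, and 0 regions had a q under 0.05. The call on chromosome 11 was lost without WT replicate 3 labelled maternal at P2 (difference 0.355), with each library name series as a covariate (0.330), with the libraries whose table and label differ left out (0.361), and with the litters grouped by table membership (0.211, limma adjusted p = 0.534 after Benjamini-Hochberg adjustment), which called no region (0). Regions on chromosome 6 from 25610361 to 25610553 and on chromosome 3 from 35480157 to 35480585, next by p, differed by 0.279 (SE 0.0482) and -0.155 (SE 0.0272) without passing the threshold.

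For age in WT libraries, limma with Benjamini-Hochberg adjustment called 0 of 16243 regions, with 1046 at unadjusted p under 0.05. Ages are as labelled, and the age labels of WT libraries whose table and parental label differ may be in doubt. The comparisons of age hold only as far as these labels do. The lowest p values belonged to regions on chromosome 17 from 13553227 to 13554385 (0.752 ± 0.0386 at P9, 0.887 ± 0.0405 at P2), chromosome 5 from 172365974 to 172366452 (0.408 ± 0.0911 and 0.143 ± 0.0939) and chromosome 10 from 64360900 to 64361897 (0.593 ± 0.0916 and 0.344 ± 0.0782; SD, n = 5 at P9 and 7 at P2). No second tool was run on the methylation levels.

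Mean methylation over all regions of a table showed no difference past the threshold between these groups of libraries, and for the deletion labelled maternal the exact test could not go below 0.05. Deletion libraries stood at 69.8% ± 0.221 and WT libraries at 69.9% ± 0.911 with the label maternal (SD, n = 4 each; exact permutation p = 0.65, smallest possible 0.05). With the label paternal they stood at 69.8% ± 0.480 and 69.7% ± 1.47 (SD, n = 5 each; exact permutation p = 1, smallest possible 0.0167). WT libraries labelled maternal stood at 69.6% ± 0.889 (n = 5) and those labelled paternal at 69.4% ± 1.38 (SD, n = 7; exact permutation p = 0.809). P9 libraries stood at 69.6% ± 1.46 (n = 5) and P2 libraries at 69.4% ± 1.01 (SD, n = 7; exact permutation p = 0.843). After Benjamini-Hochberg adjustment over these 4 exact tests each p was 1. Single libraries moved the deletion differences: without WT replicate 3 labelled paternal at P9 the paternal difference was -0.579 percentage points (exact permutation p = 0.0333), and the maternal difference was -0.485 points without WT replicate 3 labelled maternal at P2 (exact permutation p = 0.05) and 0.277 points without WT replicate 1 of that group (exact permutation p = 0.5).

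Within the 4 mitochondrial regions of the control table, mean levels followed the library name series. They were 50.2% to 66.3% in the 2 WT libraries with names starting JL3, 8.53% to 18.4% in the 4 starting JL4 and 0.822% to 2.45% in the 6 starting JL5. With the JL5 series against the others as a covariate, limma with Benjamini-Hochberg adjustment called the same number of regions, 1 for WT litters and 0 for deletion and age, and with each series as its own covariate it called 0 for WT litters. The JL5 series holds both parental labels, but the others were not balanced, since all JL3 libraries are labelled maternal and all JL4 libraries paternal.

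**Figure D3:**
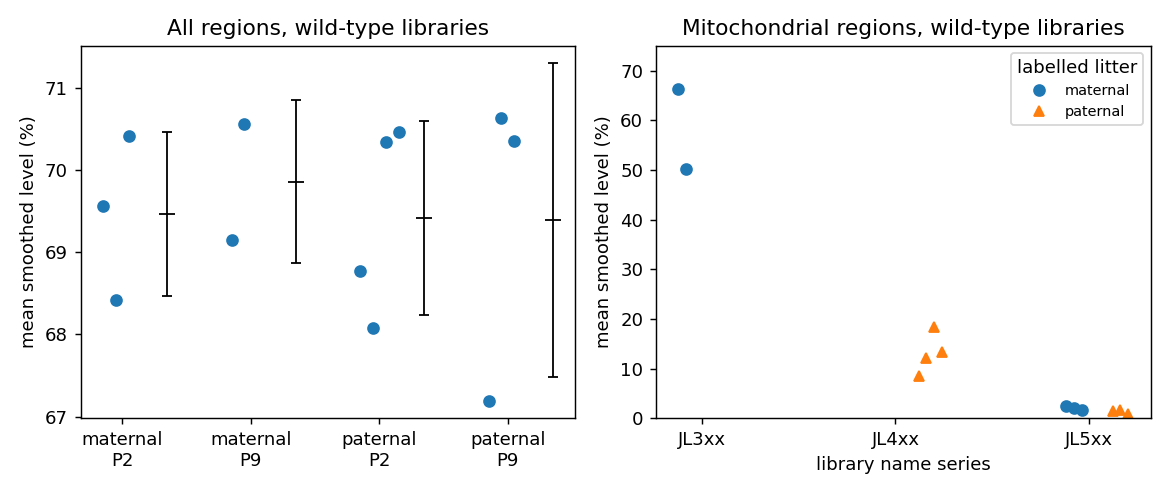
Mean smoothed methylation level in percent (vertical axes) of the 12 WT DNA libraries of the control table, over all regions by parental label and age (left; points are libraries, bars mean and SD) and over the 4 mitochondrial regions by library name series (right; circles labelled maternal, triangles labelled paternal). Over all regions the groups overlap between 67.2% and 70.6%, while over the mitochondrial regions the JL3 libraries lie at or above 50.2% and the JL5 libraries at or below 2.45%.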

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

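The tests of exchanged labels, depth, library name series and kind of litter given here were chosen only after the results were seen. Of 16 groups of 4 to 7 library means tested for a library apart from the rest, 4 had such a library, where chance gives about 1 in 20.

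Accessions changed with age in opposite directions in cortex of the different litters: 3876 accessions had an age effect that differed between WT cortex labelled maternal and paternal. A difference in depth is argued against, because with all cortex libraries thinned to the same total the age score of cortex labelled paternal was still -0.94 (P9 minus P2). An exchange of age labels in the cortex labelled maternal is argued against too, since its score rose by 0.86, as in hypothalamus. An exchange of age labels in the cortex labelled paternal is a candidate explanation, as the score there was -0.97, opposite in sign and similar in size to the other sets, in all 6 libraries of each age. A true difference between litters in how cortex changes with age was not tested and stays open. Such a difference would not extend to hypothalamus, where 111 accessions were called for age with both labels, all in the same direction. The name series is JL6 for all cortex RNA labelled maternal and JL7 for all labelled paternal, at both ages. A shift shared by a whole series would thus cancel in P9 minus P2, which argues against it as the source of the reversal. Anything in a series that acts differently at the ages stays open.

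NM_173010 had a deletion effect in hypothalamus that differed by 2.644 on the log2 scale between the labels maternal and paternal. A fall hidden by the lower depth of the libraries labelled maternal is argued against, since the lower end of the 95% interval of the log2 fold change over both ages is -0.66 there, far above the change of -2.77 in libraries labelled paternal. An exchange of parental labels in hypothalamus cannot be told apart from a true parental difference: NM_027915 exceeded 50 CPM in all 6 hypothalamus libraries labelled maternal at P2, as in cortex, but nothing in the files ties that accession to a parent. In each tissue it exceeded 50 CPM in no library labelled maternal at P9. With the label paternal it did so in 1 of 3 P2 WT and 1 of 3 P9 deletion libraries of each tissue. An effect of the parent that passed on the deletion stays open as well, and so does what NM_173010 is. If it stood for the deleted gene, its levels could serve as a check of the labels. Mainly maternal expression in neurons would then have it fall with the label maternal and little with the label paternal, the reverse of hypothalamus here. That would put in doubt the parental labels of hypothalamus first. Wrong genotype labels in hypothalamus labelled maternal could account for the missing fall there, but not for the fall with the label paternal. The genotype labels of cortex labelled maternal, where WT and deletion libraries overlap, would be in doubt too. In cortex labelled paternal overlap alone would raise no doubt, but the low levels of some WT libraries there would.

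Mitochondrial regions had a mean level of 65.9781% in WT replicate 1 labelled maternal at P2 in the maternal table, where the other 3 WT libraries of that table labelled maternal had 1.77% to 2.49%. The level follows the library name series: in the control table the lowest JL3 library lay 31.8663 percentage points above the highest library of the other series. The kind of litter alone is argued against, since control-table libraries labelled maternal ran from 1.74% in JL5 to 66.3% in JL3. Within the JL5 series the labels maternal and paternal differed by 0.8297 points. There all libraries labelled maternal (1.74% to 2.45%) lay above all labelled paternal (0.822% to 1.61%). These levels are near the floor, so a part of the litter in the gap between series stays open. A batch difference in bisulfite conversion or in reads from mitochondrial DNA is a candidate explanation that these levels, without coverage, could not separate.

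Over X-linked regions, that same WT replicate 1 labelled maternal at P2 had a mean of 61.5641% in the maternal table, against 60.2% to 60.3% in the other 3. WT replicate 1 labelled maternal at P9 had a mean of 60.8675% over X-linked regions of the control table, against 62.1% to 62.6% in the other 4 WT libraries labelled maternal. Over all regions of the paternal table, WT replicate 3 labelled paternal at P9 had a mean of 67.0884%, against 70.3% to 70.4% in the other 4 WT libraries labelled paternal.

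Other splits of the same libraries were counted for each comparison. For age in hypothalamus (763 accessions, highest other split 472, 1 of 100 splits) no other split gave as many calls. That argues against a chance split of these libraries. For WT litters in hypothalamus (73, highest other 90, 2 of 100 splits) the share is under 0.05. Yet another split gave more calls and the count ran from 9 to 344 with a library left out, so the count does not exclude chance. In separate deletion pups 43 of the 73 were called again, all in the same direction. Splits move single libraries and no label names a litter, so they do not cover chance between litters. The deletion pups do not cover it either, because they were litter-matched to the WT pups. For WT litters in methylation (1 region, highest other 1, 4 of 100 splits) the share is under 0.05, but it rests on a single call among preselected regions that other splits also reach and that several settings end, so little can be read from it. By the count alone, chance cannot be excluded for the hypothalamic deletion effect labelled paternal over both ages (1, highest other 506, 15 of 100 splits) or the parental difference in hypothalamus (1, highest other 34, 8 of 100). For WT litters in cortex (1403, highest other 2600, 10 of 100) the splits cannot decide. They mix libraries whose age effects run in opposite directions, so high counts among them can come from age. These counts take any accession and do not test NM_173010 itself. Its call over both ages held in all 16 planned settings and its parental difference in all 27, of which 12 and 24 leave a library out. Such refits of the same libraries are no test of chance, and both calls were lost with thinned counts. The counts of splits also do not use the deletion pups, separate libraries in which 1216 of the 1403 cortex accessions were called again, all in the same direction, where independent lists give 271 in the same and 249 in opposite directions. That argues against a chance split of single WT libraries in cortex. Deletion and WT pups were litter-matched and share the name series and the fit, so chance between litters or series is not covered. In hypothalamus labelled paternal at P9, the split with 468 calls, against 1 for the real split, set WT replicate 1 and deletion replicates 1 and 2 apart from the rest. Splits with so many more calls than the real one point to a structure of the samples.

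With a real count of 0, every split is as large whatever the libraries hold, so the splits are no test of chance in these comparisons. The highest other split had 0 calls for the deletion labelled maternal over both ages in hypothalamus (100 splits), and 34 and 323 for the age dependence labelled maternal and paternal. In cortex it had 30 and 19 for deletion over both ages labelled maternal and paternal, 11 and 23 for their age dependence, 1 for the parental difference and 1763 for age. In methylation it had 1 region for the deletion labelled paternal (60 splits) and 7 for age (100 splits). Splits are too few for a share under 0.05 in the deletion contrasts at a single age, with 10 splits each: real and highest other counts were 0 and 0 at P2 and at P9 labelled maternal and 1 and 0 at P2 labelled paternal in hypothalamus, and 0 and 0 (maternal P2), 0 and 48 (maternal P9), 0 and 0 (paternal P2) and 0 and 17 (paternal P9) in cortex. They are also too few for methylation by the deletion labelled maternal (20 splits, 0 and 1).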

How the results depend on the processing

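The settings with thinned counts, within 1 kind of litter, with NR_137294 removed, with each name series, with all 12 libraries of a methylation table, without libraries whose table and label differ, and by table membership were chosen after seeing the data. Of 123 settings for counts of called accessions (libraries left out singly not included), 84 stayed within 1.5 times, and of 240 with a library left out, 214 did. No named accession turned its direction in 91 settings and 180 with a library left out, and 17 and 33 of these ended its call. Settings in which the filter dropped the accession are not among these. NR_074088 and NM_001316345 had a value in 6 of 12 fits with a library left out. Named regions kept direction in all settings, and their side of the threshold in 78 of 84 and 123 of 126. Scaling by DESeq2 size factors and removal of NR_137294 changed no count by over 1.5 times. Parental differences use all 24 libraries, so they have no value with only the libraries of the contrast, and the gene lists gave no value. For methylation by deletion, each name series as its own covariate has no value beside the JL5 series against the others, because the libraries tested hold only JL5 and a single other series. No paired analysis was possible because the labels carry no replicate numbers, and those used here were assigned in the order of the sample records. The cause was not tested for any change given here, except that thinning lowers depth and leaving libraries out lowers n.

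DESeq2's Wald test called 1 in hypothalamus for the deletion labelled maternal at P9, 2 for that labelled paternal over both ages and 178 for WT litters. In cortex it called 1 (maternal P2), 9 (maternal P9), 9 (maternal, both ages), 1 (paternal P9), 3 (parental difference) and 1 (age). With no filter on low counts, hypothalamus gave 1 (maternal P9), 1 (maternal, both ages), 2 (paternal P9), 3 (paternal, both ages) and 344 for WT litters (49 higher, 295 lower, with the median of all accessions at -0.32). Cortex then gave 7 (maternal P2), 56 (maternal P9), 45 (maternal, both ages), 15 (paternal P9), 1 (paternal, both ages), 2 (paternal age dependence), 16 (parental difference), 2329 (WT litters, 1852 higher and 477 lower) and 13 (age). With only the libraries of the contrast, hypothalamus gave 1 (maternal P9) and 0 (paternal P9), and cortex 2 (maternal P2) and 1 (maternal P9). Thinned, hypothalamus gave 0 (paternal P2), 3 (paternal P9, all higher), 1 (paternal, both ages, a rise), 1 (parental difference, a fall), 1 (paternal age dependence), 18 (WT litters) and 228 (age). None of the deletion calls was NM_173010. Thinned cortex gave 2 (maternal P2), 5 (maternal, both ages) and 547 (WT litters). Age within litters labelled maternal and paternal gave 214 and 347 in hypothalamus and 2567 and 2457 in cortex.

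With a library left out, counts in hypothalamus ran from 0 to 1 (maternal age dependence, 1 without P9 deletion replicate 3), 1 to 2 (paternal, both ages, 2 without WT replicate 1 of either age), 9 to 344 (WT litters) and 465 to 869 (age, 465 without WT replicate 1 labelled maternal at P2). In cortex they ran from 0 to 3 (maternal P2, 3 without deletion replicate 1), 0 to 321 (maternal P9), 0 to 220 (maternal, both ages), 0 to 52 (parental difference), 0 to 13 (paternal P9, 13 without WT replicate 2), 0 to 1 (paternal age dependence) and 0 to 2 (age), the highest of maternal P9, both ages and the parental difference all without WT replicate 3 labelled maternal at P9. WT litters in cortex ran from 940 to 1945.

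For methylation, the deletion labelled paternal gave 1 region with all 12 libraries. WT litters gave 2 on the logit scale, 3 with no variance trend, and 0 with each name series, without libraries whose table and label differ, and by table membership. With a library left out WT litters ran from 0 to 3 and age from 0 to 1. Differences in mean level, none past the threshold as reported (the maternal one could not be), turned sign with the median over regions for the deletion labelled paternal (-0.0246 points), WT litters (-0.198) and age (-0.183). With a library left out they ran from -0.485 to 0.277 (deletion, maternal), -0.579 to 0.407 (deletion, paternal), -0.203 to 0.521 (WT litters) and -0.153 to 0.752 (age).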

Other observations

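The comparisons of accession counts above a level given here were chosen only after the data were seen. NM_027915 was either clearly counted or nearly absent: 16 of the 48 RNA libraries had 53.5 to 146 CPM, and the other 32 had at most 12.5 CPM. It was above 50 CPM in all 6 libraries labelled maternal at P2 and in 0 of the 6 labelled maternal at P9, in each tissue. Among libraries labelled paternal it was above 50 CPM in 4 alone. In hypothalamus these were P2 WT replicate 2 (83.1 CPM) and P9 deletion replicate 2 (96.7 CPM), and in cortex P2 WT replicate 1 (64.9 CPM) and P9 deletion replicate 1 (63.7 CPM). NM_173010 stood at 53.2 and 2.61 CPM in that pair of hypothalamus libraries. In that pair of cortex libraries NM_173010 stood at 14.5 and 45.3 CPM. In the same order, age scores were -0.48 and 0.47 in hypothalamus and 0.36 and -0.61 in cortex. An exchange of age alone in cortex would place NM_027915 above 50 CPM in P9 WT and P2 deletion libraries, unlike in hypothalamus. This rests on a single library per group and cannot decide between errors of age and genotype labels. No label ties a cortex library to a hypothalamus library.

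NR_ accessions took different shares of the age calls. In hypothalamus, 2.30% of accessions that rose with age were NR_ accessions against 8.58% of the others tested (odds ratio 0.251, 95% interval 0.118 to 0.470), and 13.4% of those that fell against 7.80% (odds ratio 1.83, 95% interval 1.28 to 2.57), by Fisher's exact test. In cortex labelled maternal, 4.63% of those that rose and 17.3% of those that fell were NR_ accessions. In cortex labelled paternal these were 21.7% and 3.13%. The directions there rest on age labels that may be exchanged. With P2 and P9 exchanged, the shares would be 3.13% of those that rose and 21.7% of those that fell, in the order of the other sets.

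Regions listed in more than 1 methylation table did not carry the same level for the same library. The control and maternal tables share 239 regions and 6 libraries, with a mean absolute difference of 7.43 percentage points, and 12.7% of levels lay within 1 point. The control and paternal tables share 226 regions, with a mean absolute difference of 6.31 points and 12.6% of levels within 1 point. Over X-linked regions of the control table, WT replicates 2 and 4 labelled paternal at P2 had means of 49.1% and 52.9%, and the other 10 WT libraries had 57.3% to 62.6%.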
